A study of Rattus norvegicus with 3 samples.

How the data were processed

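Gene expression was measured in neonatal rat ventricular cardiomyocytes on 3 Agilent one-colour arrays, 1 per group. Per the labels' protocols, cells received an empty vector (control), an expression vector for 11β-HSD1 (HSD1), or that vector together with the 11β-HSD1 inhibitor BVT.2733 (HSD1 plus BVT). RNA came from a pool of cells per group and was labelled with Cy3. Doses, exposure times and the number of cultures in a pool are not given in the sources used here.

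Per the file headers, the arrays were scanned in 1 channel and extracted with Agilent Feature Extraction version 11.0.1.1, which the submitters' processing notes also name. The deposited intensity values are the processed signal of each spot, background-subtracted and on a linear scale, and the median brightness of the spot and of its local background. The authors also deposited a table of log2 values, 1 row for each of 30423 probes. Its values have the form that quantile normalization gives: sorted, the 3 columns differ by at most 0.01 at 26991 of 30423 ranks, and the other ranks all lie at or below 2.74, where they differ by up to 0.34. It correlated with the log2 processed signal across probes at r = 1.00 on each array, with slopes of 0.98 to 1.00 and no centring per gene, and the software behind it is not given in the sources used here. The headers place the control and HSD1 arrays in scan 1 and the inhibitor array alone in scan 2.

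The main values are log2 of the processed signal minus the array's percentile 75 of it, which was 1320 in control, 1169 in HSD1 and 1549 in HSD1 plus BVT. Control spots and spots marked as outliers (311, 409 and 363 in the same order) were left out, and the spots of a probe were averaged. The files name probes by accession. Of 30367 probes, 18005 matched 1 gene each through a RefSeq table of assembly GRCr8, and 12362 did not match. The array's probes were annotated on an older build, so no coordinates are given. This left 15155 genes, of which 12562 had 1 probe; for the others the probe with the highest mean signal was used. Of these genes, 11600 were well above background on all 3 arrays. No spot was saturated, and 82.0%, 82.5% and 81.2% of spots were well above background in control, HSD1 and HSD1 plus BVT.

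With 1 array per group there is no estimate of the spread between cultures, so no test was run and no p-value is given. A gene was called by size alone, at 2-fold or more, among genes well above background on both arrays. Of genes measured on 1 of the 2 arrays, a lower bound of the fold is given against the lowest signal well above background on the other array, or the gene's own signal where that was higher. The only error available is technical. Across 1390 probes printed 10 times, the median SD between spots was 0.046 in control, 0.049 in HSD1 and 0.043 in HSD1 plus BVT (log2), and a ratio of single spots had an SD of 0.069 for HSD1 against control. That SD was 0.12 among the dimmest 25% of these probes. It covers the array measurement and not the cultures, transfections or pools, and the number of arrays limits the precision. In data simulated for HSD1 against control over 11600 genes, all 67 genes changed 3-fold and all 66 changed 4-fold were called, as were 4 of 67 changed 1.5-fold and 11 of 11400 unchanged ones. The spread between cultures, transfections or pools is unknown and could not enter this simulation. These shares therefore do not give the rate of false calls in the real data.

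Before the data were examined, 30 gene lists were fixed, 23 of pathways and 7 of cell types, along with the 3 comparisons, the alternatives other than the repair of normexp described here, and the rule for named genes. A list is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on signal, which describes these arrays only. With 30 lists and 3 comparisons, some medians stand apart by chance, and the lists that lead the account were picked after their values were seen. The rule names, per comparison, the 8 highest and 8 lowest genes with a symbol that were called by the main values, by quantile normalization and by the normexp setting, whose brighter array was above the median signal and whose other probes did not oppose them; up to 2 called genes per list and direction, or the most extreme member of a list without any; 15 genes fixed by name; the 3 highest bounds per direction; and the genes that moved back. Not every gene the rule picks is reported here. Comparisons that share an array share its chance values. Their relation is therefore set beside 1000 simulated sets of 3 arrays that vary independently. These sets shuffle each array's observed deviations among genes of like signal, so real effects of vector and inhibitor are part of them. They also bring the variances of the arrays closer together: that of the HSD1 array was 0.037 observed and 0.052 simulated.

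The planned normexp setting could not be run as written in 2 respects. It named the mean spot signal, which is not a column of the files used here, so the median signal was used. It was then void on the HSD1 array, where 5 spots had a local background above 100 (highest 337615, array median 19.5). After it the middle 50% of that array's log2 values lay between 10.78 and 11.07, against 6.47 and 10.30 in control. An alternative chosen after seeing the data set the local background of spots marked as non-uniform (4, 18 and 58 spots on the 3 arrays) to the array's median, which gave 6.53 and 10.15 in HSD1. This repaired setting also stands in for normexp in the rule for named genes, which therefore differs from the rule as planned. Both normexp settings add an offset of 50 to the corrected signal, which shrinks the ratios of dim genes by construction. Other alternatives were quantile normalization, median centring, cyclic loess, the authors' values, 3 filters on dim probes, the median over probes, outlier spots kept, and thresholds of 1.5-fold, 3-fold and 4-fold. Tools were R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.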

Results

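Transcript levels were compared between 3 pools of neonatal rat ventricular cardiomyocytes, each read on 1 array. The study set out to find how 11β-HSD1 acts on cardiomyocyte hypertrophy. 11β-HSD1 is the enzyme that regenerates active glucocorticoid from its inactive 11-keto form, and BVT.2733 is an inhibitor of it. The arrays resembled each other closely across 22139 probes, with r = 0.99 for each pair. No group had a replicate, so every difference compares 2 arrays of pooled cells. Genes counted as higher or lower differed 2-fold or more.

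Hsd11b1, the targeted gene, gave normalized log2 signals of 3.39 in control, 3.86 in HSD1 and 3.76 in HSD1 plus BVT. This was 1.39-fold above control with the vector and 1.30-fold above control with vector and inhibitor, both under the 2-fold threshold. The log2 ratio of 0.47 with the vector lay inside the range of -0.57 to 0.79 that held 95% of the 11876 genes. That range is a spread across genes and not an error of this gene. The ratio was larger than the technical SD of 0.069 for a ratio of single spots. The spread between cultures is unknown, so a difference of this gene due to the vector was not shown. The ratio rests on 1 probe. The species of the vector's insert is not given in the sources used here, so whether the probe reads the vector's transcript is unknown.

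With the 11β-HSD1 vector, genes induced by the glucocorticoid receptor were higher than in control, and genes of the interferon response were lower. Of 30 measured glucocorticoid receptor targets, 8 were higher and 1 was lower, 28 had a ratio above 0, and the median log2 ratio was 0.59, above the medians of all 10000 random lists. Sult1a1, a sulfotransferase, was 7.39-fold higher. Fkbp5, a co-chaperone of the receptor, was 4.22-fold higher, the kinase gene Sgk1 was 2.44-fold higher, and Tsc22d3, which encodes the leucine zipper protein GILZ, was 2.02-fold higher. Zbtb16 was not well above background in control and at least 3.85-fold higher with the vector, while Per1 stood at 1.17-fold. Mertk, a receptor tyrosine kinase of phagocytes, was the member that went the other way, 3.48-fold lower. The receptor genes Nr3c1 and Nr3c2 had log2 ratios of -0.19 and -0.31, and the other probe of Nr3c1 gave -0.80. In the list of mineralocorticoid receptor targets, which shares 4 genes with the glucocorticoid list, 3 of 13 were higher and the median was 0.26.

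All 28 measured interferon response genes had ratios below 0, and 11 were lower (median -0.90, below all random lists). Isg15, a ubiquitin-like protein, was 4.02-fold lower, Rsad2 3.54-fold, Ifit3 2.85-fold and Oasl2 2.74-fold. Of 22 inflammatory mediators, 4 were lower and none higher (median -0.41, below all random lists). The cytokine genes Il1b and Il6 were 2.99-fold and 2.89-fold lower. Gdf15, a stress-induced cytokine of the TGF-beta family, was 2.66-fold lower.

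The highest ratios under the naming rule belonged to Gal, which encodes the neuropeptide galanin and was 30.0-fold higher, and to Orm1, an acute-phase plasma protein, 17.7-fold higher. The other probe of Gal gave a log2 ratio of 4.83 beside 4.90. The tyrosine kinase gene Txk followed at 7.41-fold, Cldn1, a tight junction claudin, at 6.76-fold, Tnfrsf17 at 6.48-fold, and A2m, the protease inhibitor alpha-2-macroglobulin, at 5.28-fold. Acsbg1, an acyl-CoA synthetase, had a log2 ratio of 2.68. Genes measured on 1 of the 2 arrays added bounds: Actrt1 was at least 11.6-fold higher with the vector and Ucn3 at least 8.72-fold lower.

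Hypertrophy markers lay close to control. Of 21 measured, none was higher, 1 was lower, which was Il6, and the median was 0.09 (percentile 92.0 among random lists). The natriuretic peptide gene Nppa was 1.18-fold above control and Nppb 1.03-fold below it. The myosin heavy chain genes Myh7 and Myh6 had log2 ratios of 0.13 and 0.09, and the skeletal actin gene Acta1 one of 0.04. Sarcomere genes had a median of 0.07 and calcineurin and growth signalling genes one of 0.05, with no member 2-fold from control. Among markers of cell types, the 10 measured endothelial genes all lay above 0 (median 0.58, above all random lists), with Sox17 2.09-fold higher. Fibroblast markers, beside the inflammatory mediators, had a median of -0.12 (percentile 0.3), with 12 of 17 below 0 and none 2-fold lower; the most extreme was Lum, at -0.88. The median was 0.09 for cardiomyocytes (percentile 92.3) and 0.17 for macrophages and leucocytes (percentile 96.8), whose member Mrc1 was 2.96-fold higher.

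In all, 224 of 11876 genes differed 2-fold or more, 159 higher and 65 lower. The split was 121 to 88 after quantile normalization, 114 to 95 after cyclic loess and 113 to 90 in the authors' values, and the repaired normexp setting called 93 genes and put Mertk at -0.52, Mrc1 at 0.81 and Sox17 at 0.33, under 2-fold. Tsc22d3 lay between 0.94 and 0.99 on the log2 scale in the 5 other scalings, just under 2-fold. Of 25 called genes with a further measured probe, that probe gave the same direction for 24 and also 2-fold for 16 (r = 0.59 across 1913 genes with further probes).

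**Figure D1:**
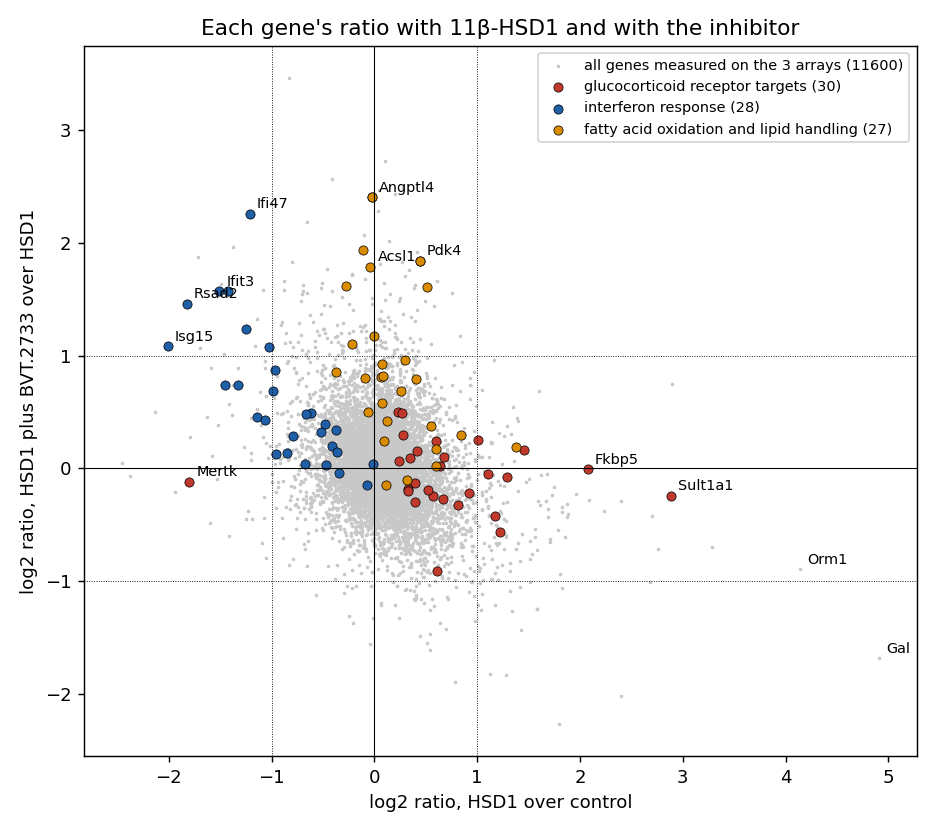
Each point is a gene, with the log2 ratio of HSD1 over control on the horizontal axis and of HSD1 plus BVT over HSD1 on the vertical axis; dotted lines mark 2-fold. Interferon genes (blue) lie mostly at the upper left, glucocorticoid receptor targets (red) mostly to the right near 0 on the vertical axis, and lipid genes (orange) mostly above 0 on the vertical axis. The 2 axes share the HSD1 array, which alone tilts the cloud downwards.

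Adding the inhibitor to the vector asks which of these differences it changes. Genes of fatty acid oxidation and lipid handling were higher with the inhibitor than with the vector alone: 9 of 28 were higher, none was lower, 26 had ratios above 0, and the median was 0.81, above all random lists. Angptl4, a secreted inhibitor of lipoprotein lipase, was 5.30-fold higher. The thioesterase gene Acot2 was at 3.82-fold, Pdk4, a kinase that inhibits pyruvate dehydrogenase, at 3.58-fold, and Acsl1, an acyl-CoA synthetase, at 3.45-fold. Pdk4 had a log2 ratio of 0.63 in the repaired normexp setting, under 2-fold. Cholesterol synthesis genes had a median of 0.59, also above all random lists, with 19 of 20 above 0 and no member 2-fold away. Its most extreme member was Insig1, at 1.78-fold. With the vector this list was already below all random lists against control (median -0.19), so its ratio to HSD1 starts from low values on that array. Against control, cells with vector and inhibitor had a smaller median of 0.32 for it, above all random lists, with 17 of 20 above 0.

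Glucocorticoid receptor targets stayed close to their level with the vector alone (median -0.05, percentile 13.6). The 2 members that were higher, Angptl4 and Pdk4, also belong to the lipid list. Of the 8 targets that were higher with the vector, none was lower with the inhibitor, their median was -0.06, and 6 remained at least 2-fold above control. Genes picked for being high against control tend to stay high in another ratio to it: of all 152 genes higher with the vector, 68 stayed so, against 53.9 of 134.4 in simulated independent arrays. Their median against HSD1 was -0.42, against a simulated -0.36 (95% range -0.46 to -0.26). No such value was simulated for these 8 alone, and the simulated HSD1 array varied more than the observed one. Fkbp5 had a log2 ratio of -0.01 against HSD1, Sgk1 one of -0.08 and Tsc22d3 one of 0.25.

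Interferon genes were higher with the inhibitor: 7 of 28 were 2-fold or more above the vector alone and none below it (median 0.44, above all random lists). All of these 7 were among the 11 that were lower with the vector, and the 11 had a median of 1.08. Genes picked for being low on the HSD1 array tend to come back in a ratio that divides by it: for all genes lower with the vector, the median was 0.46, and arrays that vary independently gave 0.57 (95% range 0.40 to 0.73). No such value was simulated for these 11 alone, and the simulated HSD1 array varied more than the observed one. Ifi47, a GTPase induced by interferon, was 4.79-fold higher and Usp18, which removes Isg15 from proteins, 2.98-fold. Inflammatory mediators had a median of 0.12, which was -0.06 in the repaired normexp setting. Of 21 NRF2 and antioxidant genes, 3 were higher (median 0.22, percentile 99.99), among them Gsta2, a glutathione transferase, at 3.90-fold and Hmox1, heme oxygenase 1, at 2.33-fold. Gsta2 was 2.59-fold lower with the vector than in control, so its ratio to HSD1 starts from a low value on that array. With vector and inhibitor it stood 1.51-fold above control, and Hmox1 2.13-fold.

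Other high genes were Lrrc39 at 4.21-fold, Mtarc2 at 3.55-fold, Cacng7 at 3.51-fold and Tppp3 at 3.12-fold. Of genes measured on 1 of the 2 arrays, Defb49 was at least 27.7-fold higher, Aqp7, an aquaporin, at least 10.5-fold and Defb41 at least 8.04-fold. Defb49 and Defb41 are beta-defensins, a family not expected in heart cells. Actrt1 was at least 11.0-fold lower. The 3 highest bounds for lower genes, Actrt1, Or12k5 and Serpina6, were also the 3 highest for higher genes with the vector. These 3 genes were thus measured on the HSD1 array alone. The 5 genes that met the naming rule's conditions for lower genes were Gal, 3.22-fold lower, Spock2, 2.76-fold, the cholesterol exporter gene Abcg1 and the inhibin gene Inha, both 2.59-fold, and Elane, 2.12-fold. Hypertrophy markers had a median of -0.06 with none 2-fold away. Nppb had a log2 ratio of 0.58 and Nppa one of -0.15. Smooth muscle and pericyte markers had a median of -0.35, below all random lists, with Rgs5 2.15-fold lower, or at -0.71 on the log2 scale in the repaired normexp setting. Cell cycle genes had a median of -0.20, also below all random lists. Cardiomyocyte markers had a median of 0.06 (percentile 84.3) and fibroblast markers one of -0.11 (percentile 2.93). Endothelial markers had one of -0.16 (percentile 5.28), with 8 of 10 below 0 and Tek 2.07-fold lower, or at -0.54 on the log2 scale in the repaired normexp setting.

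Of 11703 genes, 244 differed 2-fold or more, 176 higher and 68 lower. Among the 176 were 39 olfactory and vomeronasal receptor genes, 4 of them above the median signal. The repaired normexp setting called 76 genes, and with no filter on dim probes the split turned to 518 higher and 1015 lower. The inhibitor array was the only one in its scan, so scan and inhibitor cannot be told apart here or in the comparison of the inhibitor group with control; of 21 called genes with a further measured probe, that probe gave the same direction for 16 and also 2-fold for 5 (r = 0.39 across 1883 genes).

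**Figure D2:**
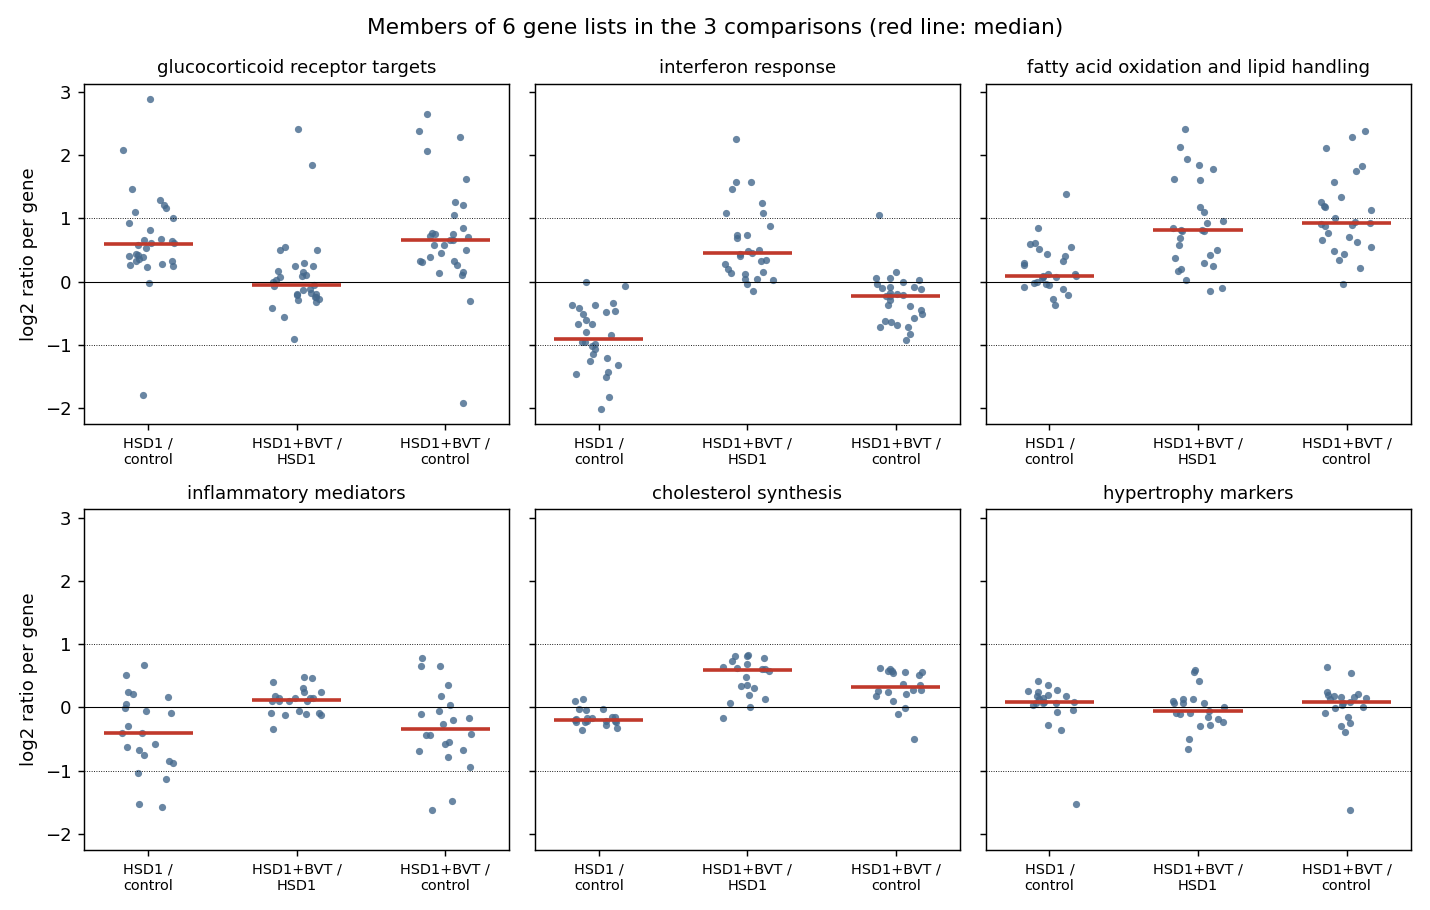
Log2 ratios of the measured members of 6 gene lists in the 3 comparisons, with 1 point per gene, a red line at the median and dotted lines at 2-fold. The interferon median goes from -0.90 to 0.44, the lipid median from 0.10 to 0.81, and the glucocorticoid target median from 0.59 to -0.05 between the vector's and the inhibitor's comparison.

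Set against control, cells with vector and inhibitor kept most of the raised glucocorticoid targets high and had lipid genes high as well. Of 30 glucocorticoid receptor targets, 8 were higher and 1 lower (median 0.66), and of 27 lipid genes 12 were higher and none lower (median 0.93). Both medians lay above those of all random lists. Of these 8 targets, 6 were also higher with the vector alone. The others were Angptl4 and Pdk4, which count as lipid genes too and had log2 ratios of -0.02 and 0.44 with the vector alone. Sult1a1 was 6.25-fold higher, Fkbp5 4.19-fold and Angptl4 5.22-fold. Cpt1b, the muscle enzyme that carries fatty acids into mitochondria, was 4.34-fold higher by its brightest probe, with a log2 ratio of 0.95 by its other probe. Of interferon genes, 1 of 29 was higher and none lower, though 24 lay below 0 (median -0.22). Of inflammatory mediators, 2 of 22 were lower and 16 lay below 0 (median -0.34), and both medians were below all random lists. Il6 was 3.09-fold and Il1b 2.78-fold lower.

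Txk was 12.4-fold higher than in control, Orm1 9.51-fold, Gal 9.31-fold and Aldh3a1, an aldehyde dehydrogenase, 4.89-fold. The chemokine gene Ccl11 was 3.38-fold lower, Pcp4l1 3.23-fold, Ppp2r2b 3.12-fold, and Mlf1 3.03-fold. Abcg1 had a log2 ratio of -1.58. Hypertrophy markers had a median of 0.09, which was -0.0015 after cyclic loess, and Nppb stood at 1.45-fold. Fibroblast markers had a median of -0.24, below all random lists, with 13 of 17 below 0 and Fbln1 2.27-fold lower, or at -0.66 on the log2 scale in the repaired normexp setting. Cardiomyocyte markers had one of 0.15 (percentile 97.9). Endothelial markers had one of 0.20 (percentile 81.5) with none 2-fold away, and its sign turned in the repaired normexp setting. Smooth muscle and pericyte markers had a median of -0.23 (percentile 0.08), and cell cycle genes one of -0.32, below all random lists, with 23 of 28 below 0 and none 2-fold lower. In all 433 of 11721 genes differed 2-fold or more, 345 higher and 88 lower. That split was 227 to 133 after quantile normalization, 253 to 130 after cyclic loess and 190 to 149 in the authors' values, and the repaired normexp setting called 132 genes.

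Among genes well above background on all 3 arrays, those that moved 2-fold with the vector and 2-fold back with the inhibitor were few. Genes measured on the HSD1 array alone, such as Actrt1, could not enter this count. Of 11600 genes, 19 were higher and then lower and 15 lower and then higher. Only 6 of these met the conditions of the naming rule. Gal was 30.0-fold higher with the vector and then 3.22-fold lower. Ifit3, Rsad2, Irf7 and Ifi44, all induced by interferon, and Tmem174 were lower with the vector and came back by log2 ratios of 1.57, 1.46, 1.24, 1.08 and 1.32. Because both ratios hold the HSD1 array, arrays that vary independently give such genes too: the simulation gave 42.1 on average (95% range 33.0 to 51.0) against the 34 observed. Noise between spots alone gave 1.07. The simulation shuffles the observed deviations, real effects included, and its HSD1 array varied more than the observed one. It therefore cannot tell how many of the 34 moved back by chance. The return of the interferon list was measured on the same shared array. The slope of the inhibitor's ratio on the vector's ratio across genes was -0.32, against a simulated -0.40 (-0.42 to -0.39). It was -0.42 in the repaired normexp setting, for which no simulation was run. The covariance of the 2 ratios was -0.037 against a simulated -0.052. Both follow from the variance of the HSD1 array, which was 0.037 observed and 0.052 simulated. The gaps therefore reflect the simulation's setting and cannot be read as an effect. The split of the genes that moved back was 15 to 20 after quantile normalization, 11 to 21 after cyclic loess and 3 to 7 in the repaired normexp setting.

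The comparisons of HSD1 and of HSD1 plus BVT with control shared 68 higher and 22 lower genes. Independent lists would share 4.23 and 0.42, and simulated arrays that vary independently, with control in both comparisons, shared 53.9 (95% range 45.0 to 63.0) and 23.8 (18 to 29.0). The 68 lay above the simulated range and the 22 inside it, but the observed lists of higher genes were themselves longer than simulated, with 323 against 215.8 for HSD1 plus BVT and 152 against 134.4 for HSD1, so an overlap beyond list length was not shown. The correlation of the 2 ratios across genes was 0.561, above the simulated 0.531 to 0.553, and the covariance was 0.0791, inside the simulated 0.0755 to 0.0802. The simulated variances of the HSD1 and inhibitor arrays differed from the observed ones, at 0.052 against 0.037 and 0.080 against 0.092. The gap in correlation therefore cannot be read as an effect.

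**Figure D3:**
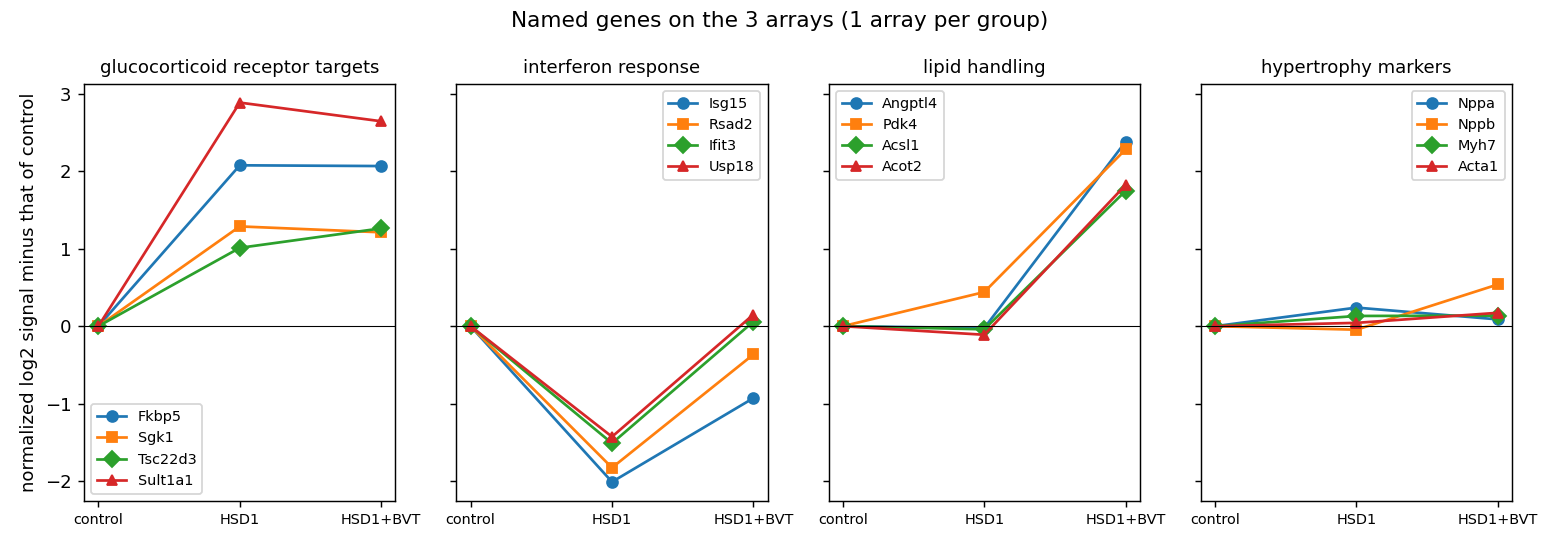
Normalized log2 signal of 16 named genes on each array, minus that of control, with lines joining the 3 arrays of a gene. Fkbp5 stands 2.08 above control with the vector and 2.07 with vector and inhibitor, Rsad2 1.83 below and then 0.36 below, and Angptl4 0.02 below and then 2.38 above.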

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

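No test in this part was chosen after the result was seen. Groups of 1 array allow no search for outlying samples and no test of a difference between groups, so what follows is signal in data that the comparisons leave out. Among probes that matched no gene name, 94 were well above background with the vector and not in control, with a lower bound of 2-fold or more. With vector and inhibitor there were 144 such probes, against 26 and 56 that were measured in control alone for the same pairs of arrays. These probes were marked because a signal appeared above control in probes the report does not use. The excess was not particular to them. Of named genes with a bound of 2-fold or more, 105 were measured with the vector alone and 26 in control alone. For vector and inhibitor against control the numbers were 135 and 67. Agilent's own control probe ETG09_35454 was above background on the inhibitor array and not in control, with a bound of 2.47 on the log2 scale. The control probe ETG10_13482 went the other way, with normalized log2 signals of -6.05 in control, -5.55 with the vector and -7.58 on the inhibitor array, where no spot of it was well above background. The bright corner spots had normalized log2 signals of -0.63, -0.44 and 0.65 in the same order. These values are given without an explanation.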

How the results depend on the processing

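The repaired normexp setting was the only alternative chosen after the data had been seen. No paired analysis was possible because each group has 1 array, and no array could be left out for the same reason. Among 90 named ratios of 2-fold or more, 826 of 871 values under the alternatives stayed at 2-fold or more, 45 did not, and 0 changed sign. For the highest and lowest genes, a call under quantile normalization and repaired normexp was itself a condition of naming. Their stability therefore does not describe all 2-fold calls, which were fewer in repaired normexp in each comparison. Of 780 medians of the lists outside the 4 leading ones, 647 kept their size, 132 moved, and 1 changed sign in a list that stood apart from random lists: erythroid genes against HSD1, 5 genes, at -0.081 in the repaired normexp setting. None of quantile normalization, median centring, cyclic loess, the authors' values and repaired normexp moved the median of all genes by more than 0.1. Signal over background limits the counts, which rose in each comparison where dim probes were let in. For the values that moved, the cause was not tested except where stated. The offset of 50 in normexp shrinks the ratios of dim genes by construction. How much of the fall in its counts this accounts for was not tested.

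Normexp as planned gave 7348, 7276 and 133 genes for HSD1 against control, HSD1 plus BVT against HSD1 and HSD1 plus BVT against control, 6618 that moved back, a slope of -1.004 and a spot SD of 0.10. Its fit was void on the HSD1 array, which the count of 133 does not use, and list medians and named genes were not run with it. Repaired normexp gave 93, 76 and 132 genes, 10 that moved back (3 higher and then lower), a slope of -0.42 and a spot SD of 0.12 against 0.046. Its medians in the same order were 0.44, -0.13 and 0.50 for glucocorticoid targets. They were -0.62 and 0.29 for interferon genes in the former 2 comparisons, and 0.68 and 0.85 for lipid genes in the latter 2. No filter on dim probes gave 1091, 1533 and 1449 genes, 509 that moved back, a slope of -0.53 and an interferon median of -0.82 for HSD1 against control; genes near background are added there by construction. With the brighter array above the median signal, which tests fewer genes, the counts were 91, 63, 121 and 12. Its glucocorticoid medians were 0.82 and 0.73 and its interferon medians -0.99 and -0.29 against control for HSD1 and HSD1 plus BVT. By construction the thresholds changed the counts, to 944, 1062, 1596 and 222 at 1.5-fold, 50, 48, 89 and 4 at 3-fold, and 17, 16, 41 and 1 at 4-fold.

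Of the other scalings, against control, quantile normalization put the interferon median at -0.98 for HSD1, and for HSD1 plus BVT the hypertrophy median at 0.0098, the glucocorticoid one at 0.55 and the interferon one at -0.31. Median centring gave 0.017, 0.59 and -0.29 for the same 3 lists with HSD1 plus BVT and 0.85 for lipid genes. Cyclic loess gave 0.51 for glucocorticoid targets and -0.99 for interferon genes with HSD1, and -0.0015, 0.57 and -0.30 for the same 3 lists with HSD1 plus BVT. The authors' values gave 0.50 and -0.99 with HSD1, then 0.013, 0.51 and -0.34 for these lists and 0.84 for lipid genes with HSD1 plus BVT.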

Other observations

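Tests chosen after the result was seen were those of the share of cardiomyocytes, of faulty probes behind the whole lipid list, of saturated spots, of silent gene families and of aryl hydrocarbon receptor targets, together with the repaired normexp setting. Several other gene lists had medians apart from those of random lists with the vector. No member was 2-fold from control among circadian clock, immediate early, calcium handling, cholesterol synthesis, unfolded protein response and cell cycle genes. The circadian clock genes had a median log2 ratio of 0.27 against control (percentile 99.3), with Npas2 at 1.60-fold. Immediate early genes had a median of 0.21 (percentile 99.9), with Fos at 1.65-fold. Calcium handling and ion channel genes had one of 0.15 (percentile 99.5), with the connexin gene Gja5 at 1.82-fold, and smooth muscle markers one of 0.20 (percentile 99.2), with Lmod1 2.19-fold higher, or at 0.77 on the log2 scale in the repaired normexp setting. Cholesterol synthesis genes had a median of -0.19, below all random lists, and 18 of 20 lay below 0. Genes of the unfolded protein response had a median of -0.11 (percentile 0.25) and cell cycle genes one of -0.10 (percentile 0.59). Ckmt2, the mitochondrial creatine kinase of muscle, was 3.01-fold higher, while its list of oxidative phosphorylation genes had a median of 0.05, whose sign turned after cyclic loess. Inside the 95% range of random lists lay the medians of genes for renin, angiotensin and endothelin signalling (0.15), autophagy (0.11), glycolysis (0.11), steroid metabolism (0.10), heat shock (-0.02) and NRF2 (-0.05). The same held for p53 (0.02), extracellular matrix (0.00), erythroid (0.12) and neural and epicardial genes (-0.06), whose signs turned in at least 1 scaling.

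With the inhibitor, extracellular matrix genes had a median of -0.09 against HSD1 (percentile 2.27) and -0.16 against control (percentile 0.02). Genes for renin, angiotensin and endothelin signalling had one of -0.16 against HSD1 (percentile 1), with 6 of 16 above 0, and 0.03 against control (percentile 52.7). Calcium handling and ion channel genes had one of 0.24 against control (percentile 99.9), with 8 of 24 below 0 and Kcne1 2.83-fold higher. Glycolysis genes had a median of 0.16 against control (percentile 98.8), with Pdk1 2.89-fold higher. Of 5 erythroid genes, Alas2 was 3.03-fold higher against HSD1, and this list's median of 0.74 was -0.08 in the repaired normexp setting.

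For the lipid genes that were higher with the inhibitor (list median 0.81), the tables argue against a signal-dependent difference between the scans, since after cyclic loess the list still lay at percentile 100 of matched random lists. A larger share of cardiomyocytes in the inhibitor's pool would lift their other markers by a similar amount, and the 18 outside the lipid list had a median of 0.060 (quartiles -0.11 and 0.23). Smooth muscle and pericyte markers had a median of -0.35 against HSD1 and fibroblast markers one of -0.11. Other differences in composition were not tested. Single faulty probes were argued against for the shift of the whole list, whose lower quartile of 0.36 lay above the 0.10 that random medians reached, while the size of single calls stays open, as only 2 further probes of the 9 called genes were measured and 50% of them, Acot2's at 1.36 but not Cpt1b's at 0.48, reached 0.5. Slide, scan and culture stay open too, since 0 scans hold the inhibitor array and another one. A candidate biological explanation is a response of PPAR-alpha target genes: 41 further targets, listed before their values as a set were seen, had a median of 0.29 with 35 above 0, at percentile 100, but an effect of culture or scan on the same genes would look alike. Many of these targets are themselves genes of fatty acid and lipid handling. Anything that raises such genes as a class would raise them too, so the result cannot single out PPAR-alpha. Of these targets, Cat also belongs to the fixed NRF2 and antioxidant list.

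Glucocorticoid targets that were higher with the vector did not, as a set, come down with the inhibitor, although the inhibitor is aimed at the enzyme. Their log2 ratios against HSD1 ran from -0.56 to 0.25, and 6 of the 8 remained at least 2-fold above control. Saturation cannot hide a fall, as 0 spots were marked saturated. Scaling does not hide it either: over 6 scalings the lowest median of the 8 targets against HSD1 was -0.091. What stays open, and was not tested, is that the enzyme was not blocked at the dose and time used, that these transcripts outlast the treatment, or that the pools differed for a reason other than the enzyme.

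Olfactory and vomeronasal receptor genes, which heart cells are not expected to use, were higher on the inhibitor array: of 367 measured, 39 were higher and 4 lower, with a median of 0.35. In the repaired normexp setting the sign turned (median -0.07), though the family still lay above all matched random lists. Being dim alone was argued against, since the family was at percentile 100 of lists of equal signal. Other families not expected in heart cells, such as beta-defensins and taste receptors, leaving out 3 genes seen before, had a median of 0.16 at percentile 99.76 (-0.11 in the repaired normexp setting), so unspecific binding or genomic DNA may contribute. This was not particular to the inhibitor sample: for HSD1 against control the receptors had a median of 0.26 (0.069 to 0.21 in the 5 other scalings) and these families one of 0.25 (0.12 to 0.24), and no biological explanation was tested.

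A response of aryl hydrocarbon receptor targets was tested as a hypothesis because Cyp1a1 was 3.26-fold and Aldh3a1 1.61-fold above HSD1 on the inhibitor array; these 2 genes were chosen after their values were seen. Of the 12 other measured targets, Gsta2 and Aldh1a3 had been seen before, and Nqo1 was a named gene. Gsta2, Nqo1 and Nfe2l2 also belong to the fixed NRF2 and antioxidant list. The 12 had a median of 0.15 at percentile 93.76, with 10 above 0 and 2 of them higher by 2-fold or more. Random lists of equal signal reached 0.19 at the upper end of their 95% range, so the wider set did not bear the hypothesis out.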
